A study of Mus musculus with 36 samples.

How the data were processed

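Accessible chromatin was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in mouse cells undergoing direct cardiac reprogramming. Per the labels, explants of neonatal hearts from CD-1 mice with an alpha-MHC-GFP reporter, which lights up when a cardiac myosin promoter is active, gave Thy1-positive, GFP-negative cells, mostly fibroblasts. These were infected with retroviruses for the transcription factors Gata4, Mef2c and Tbx5 (GMT) or for the red fluorescent protein dsRed. The GMT cells analysed here also received sb431542, an inhibitor of TGF-beta signalling, and xav939, an inhibitor of Wnt signalling, and were sorted for GFP at days 2, 3, 7, 14 and 21. The control cells received neither inhibitor and were sorted for dsRed at day 7. Every comparison with the control therefore joins the factors, the inhibitors and the sort, and all but that at day 7 also join time in culture. The labels state 3 biological replicates per condition and 2 sequencing cores, without saying which library went to which core, so a core effect could not be tested.

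The deposited table holds whole-number counts of reads per region, which were not normalized. Per the submitters' processing notes, the tools used were Bowtie2, Picard, MACS2 and edgeR, without versions, and the genome build was mm9. The settings of the alignment, duplicate removal, adapter offset and peak calling, and whether peaks were called on pooled libraries, are not given in the sources used here. The regions do not overlap, have a median width of 334 bases and are 200 bases wide in 31.3% of cases. The table as held has 1393121 lines, the last of them incomplete, and 1393120 regions were used. They lie on chromosomes 1, 10, 11, 12, 13, 14, 15, 16 and on chromosome 17 up to 79.1 Mb, so every count of peaks below covers that part of the genome, and library totals are sums over it. Of 36 samples in the labels, 18 have a column, and the other 18 (cardiomyocytes, fibroblasts with inhibitors and GMT cells without inhibitors) were not analysed here.

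Library totals ran from 2.29 to 23.2 M counts. A single region of chromosome 1 took 4.52 to 49.4% of each total, so effective library sizes came from trimmed means of log ratios (TMM, edgeR 4.0.16, R 4.3.3), and counts-per-million values (CPM) below use them. Regions were kept by edgeR's filterByExpr with its default minimum count of 10 and minimum total of 15, which left 144810 peaks, 10.4% of the regions with 79.2% of the counts. These peaks had a median width of 1490 bases, against 297 bases for those left out. All 18 libraries entered 1 quasi-likelihood fit with a mean per group (glmQLFit with robust estimation, 12 residual degrees of freedom), which gave a common biological coefficient of variation of 23.8%. Differences were tested two-sided with glmQLFTest, and a peak was called when its Benjamini-Hochberg adjusted p was under 0.05 over all peaks tested. Log2 fold changes are the fitted values with edgeR's default shrinkage. A fold against a group with no counts is given as a lower bound. It is the lower end of the exact 95% binomial interval for the ratio of summed counts, scaled by effective library sizes. Intervals and such bounds cover counting error only, since reads without molecular identifiers are not independent molecules.

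Before the data were examined, the grouping, the tests, the gene lists, the alternatives and the rule for named peaks were fixed. By that rule the text names, per comparison, the 2 called peaks with the largest rise and the 2 with the largest fall among those with all 3 libraries of 1 group above all 3 of the other, which chance gives for 10% of peaks, and with an average log2 CPM of at least 1. The share of the day 21 change present at day 2 was the median, over peaks called at day 21 against fibroblasts, of the ratio of both log2 fold changes. Windows of 100000 bases and stretches of neighbouring peaks were chosen after their values were seen. The 15 planned gene lists and the motif test were not run, because no annotation or sequence of build mm9 was used here, so peaks are given by position and no gene is named for them. Replicates were compared before averaging. The closest pair, fibroblast replicates 1 and 2, still differed by more than sampling noise (chi-square per degree of freedom 1.42), and all libraries were counted separately. Their scaling factors were 0.632 and 0.638 against 1.19 for replicate 3. The counts do not show whether these 2 came from separate cultures, so the 3 control libraries may hold fewer than 3 independent samples.

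The test was checked on simulated counts with 1 mean per peak over all groups, the dispersion trend of the data and the real effective library sizes. Of the 144810 peaks, 200 were changed, 50 at each of 4 fold sizes. Differences between libraries of a group beyond this dispersion were not simulated. For day 2 against fibroblasts it recovered 0% of 1.5-fold, 10% of 2-fold, 54% of 4-fold and 78% of 8-fold changes, with 1 false call. For day 21 against fibroblasts the shares were 0, 6, 62 and 86%. For day 3 against day 2 they were 0, 0, 52 and 72%, for day 7 against day 3 0, 12, 56 and 86%, for day 14 against day 7 0, 10, 66 and 78%, for day 21 against day 14 0, 6, 64 and 74%, and for day 21 against day 2 0, 10, 54 and 80%. With so few peaks changed, these shares do not give the sensitivity of comparisons in which many peaks differ.

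The alternatives fixed beforehand were DESeq2 1.42.0, RLE size factors, library totals alone, a trended normalization, no filter beyond 1 count, a filter at 1 CPM on average, a fit of only the groups compared, the replicate number as a block, a stricter threshold (adjusted p under 0.01 and an absolute log2 fold change above 1) and leaving out each replicate library. For the share, each replicate number was left out of all groups at once. Added after the data were seen were fits without the libraries that stand apart from their groups, with fibroblast replicates 1 and 2 summed, without the 5 regions with most counts, and with limma 3.58.1 voom and a quality weight per library, as were RLE size factors and library totals alone for summed stretches and for counts of peaks that differ at all 5 times.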

Results

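Chromatin accessibility was compared between dsRed-infected neonatal mouse cardiac fibroblasts and cells of the same kind infected with Gata4, Mef2c and Tbx5, which are transcription factors of heart development, together with inhibitors of TGF-beta and Wnt signalling. The question put to these libraries was when, along reprogramming towards induced cardiomyocytes, accessibility departs from the fibroblast state. There were 18 libraries in 6 groups of 3, namely fibroblasts and GMT cells with inhibitors at days 2, 3, 7, 14 and 21. The fibroblast libraries held 17.3, 6.77 and 2.34 M counts for replicates 1, 2 and 3. Replicates 1 and 2 were close to each other, with 49.4 and 49.3% of counts in a single region of chromosome 1 against 14.5% in replicate 3. Totals were 2.29, 10.1 and 5.92 M at day 2, 2.95, 9.89 and 23.2 M at day 3, 16.4, 10.5 and 10.8 M at day 7, 14.5, 5.36 and 4.82 M at day 14, and 7.55, 5.16 and 21.4 M at day 21. On the first principal component of log2 CPM, which held 30.3% of the variance, the fibroblasts scored 255.6 to 372.5 and all GMT libraries from -104.3 to -31.8. The second component (14.1%) set the day 2 and day 3 libraries with replicate number 1, at 262.1 and 241.1, apart from all others, which lay at or below 33.4. The third (8.70%) set day 14 replicate 3, at 233.8, apart from all others, which lay at or below 80.27. In counts below, the libraries that stand apart are those of days 2 and 3, and day 14 replicate 3 was left out separately.

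**Figure D1:**
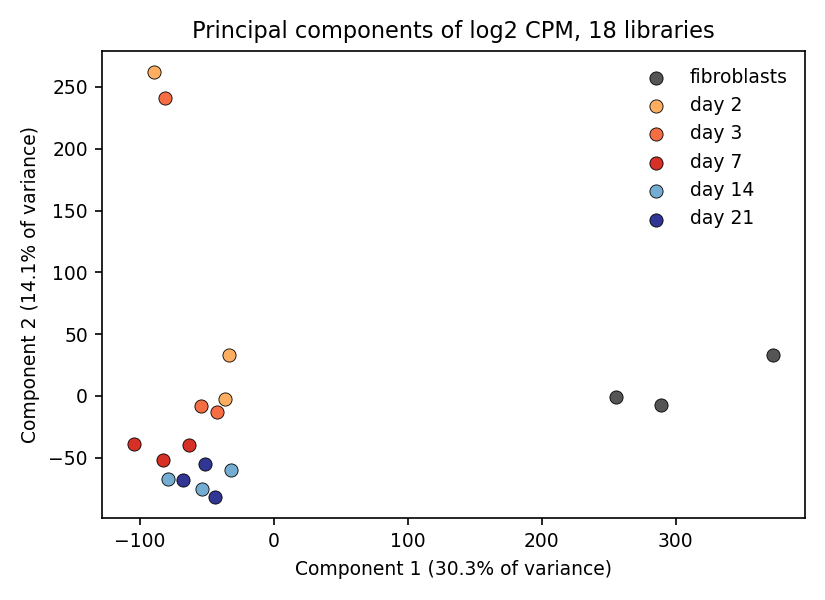
Scores of the 18 libraries on components 1 (x axis) and 2 (y axis) of log2 CPM (score units), 1 point per library, coloured by group. The 3 fibroblast libraries lie at 255.6 or above on component 1, and 1 library each of day 2 and day 3 lie at 241.1 or above on component 2.

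At day 2 accessibility already differed from fibroblasts at 29402 of 144810 peaks, 20.3%. Of these, 17683 were higher, with a median log2 fold change of 1.84, and 11719 were lower, with a median of -1.60. Peaks under 1 CPM in fibroblasts made up 45.8% of the higher ones and 32.0% of all peaks tested. Such peaks pass the filter mostly through counts in GMT libraries, and a called rise favours a low fibroblast level. The excess is thus partly built in. On chromosome 11, the peak at 57780029 to 57780707 had 0 counts in all 3 fibroblast libraries and 4.30 ± 1.39 CPM (SD, n = 3) at day 2, at least 17.28-fold higher. The peak at 88476595 to 88477346 on chromosome 1 likewise went from 0 counts to 4.02 ± 1.60 CPM, at least 15.88-fold higher. The largest falls were on chromosome 10 at 85803917 to 85805438, from 14.1 ± 4.75 to 0.932 ± 0.659 CPM (log2 fold change -3.91, SE 0.41, adjusted p 5.16e-11 by edgeR's quasi-likelihood test), and on chromosome 17 at 13090609 to 13091791, from 20.1 ± 7.70 to 1.32 ± 0.125 CPM (-3.89, SE 0.36). The count fell to 18750 without fibroblast replicate 1, to 17575 under the stricter threshold and to 11610 with no filter on low counts. The split of calls depends on the scaling: 60.1% were higher with TMM, 58.7% with RLE size factors and 53.9% with trended normalization. It was 92.3% with library totals alone, which moved the median of all peaks from -0.0027 to 0.63 on the log2 scale. Library totals include the single region of chromosome 1 with most counts. It took 49.4, 49.3 and 14.5% of counts in fibroblast replicates 1, 2 and 3. At day 2 it took 10.2, 4.52 and 35.45%.

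At day 3 the picture was similar, with 19104 peaks higher (median log2 fold change 1.80) and 12804 lower (median -1.53), 22.0% of those tested. The same peaks of chromosomes 11 and 1 led the rises, at 5.67 ± 2.23 and 4.18 ± 0.974 CPM (SD, n = 3), at least 21.43-fold and 20.11-fold higher than in fibroblasts. On chromosome 12, the peak at 41816290 to 41817379 fell from 13.8 ± 0.746 to 0.647 ± 0.1996 CPM (log2 fold change -4.22, SE 0.37, adjusted p 2.72e-13 in edgeR). On chromosome 13, the peak at 60535444 to 60537403 fell from 9.14 ± 1.33 to 0.464 ± 0.124 CPM (-4.215, SE 0.42). The 31908 calls became 20578 without fibroblast replicate 1, 20012 under the stricter threshold and 15639 with no filter, and 88.5% rather than 59.9% of calls were higher with library totals alone.

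Day 7, the only time at which the control was harvested on the same day, had the most calls, 22511 higher (median log2 fold change 1.75) and 17309 lower (median -1.58), 27.5% of peaks. The chromosome 11 peak stood at 3.67 ± 2.08 CPM (SD, n = 3), at least 16.89-fold higher than in fibroblasts. A peak of chromosome 1 at 163043787 to 163045464, also without counts in fibroblasts, stood at 3.615 ± 0.336 CPM, at least 17.18-fold higher. The peak at 71667380 to 71668440 on chromosome 1 fell from 10.5 ± 1.23 to 0.394 ± 0.354 CPM (log2 fold change -4.90, SE 0.47, adjusted p 1.41e-12 in edgeR), and that at 57879514 to 57880806 on the same chromosome from 10.4 ± 4.11 to 0.363 ± 0.121 CPM (-4.67, SE 0.42). The 39820 calls became 25718 without fibroblast replicate 1, 24876 under the stricter threshold and 21714 with no filter, and 76.2% rather than 56.5% were higher with library totals alone. Under that scaling day 7 no longer had the most calls, with 33944 against 36224, 34089, 36234 and 41486 at days 2, 3, 14 and 21. The shallowest library of day 7 held 10.5 M counts, against 2.29, 2.95, 4.82 and 5.16 M at days 2, 3, 14 and 21.

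At day 14, 18579 peaks were higher than in fibroblasts (median log2 fold change 1.82) and 14047 lower (median -1.62), 22.5% of those tested. The peaks at 57780029 on chromosome 11 and 163043787 on chromosome 1 stood at 3.25 ± 0.972 and 2.99 ± 0.332 CPM (SD, n = 3), at least 16.73-fold and 14.64-fold higher. The peak at 85803917 on chromosome 10 was at 0.5075 ± 0.470 CPM (log2 fold change -4.64, SE 0.43, adjusted p 9.30e-13 in edgeR). On chromosome 13 the peak at 105411866 to 105413328 fell from 10.3 ± 0.464 to 0.345 ± 0.365 CPM (-4.39, SE 0.45). There were 32626 calls, against 20775 under the stricter threshold and 13053 with no filter, and with library totals alone 85.3% rather than 57.0% were higher.

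At day 21, 19209 peaks were higher (median log2 fold change 1.76) and 14614 lower (median -1.565), 23.4% of those tested. The peaks at 163043787 on chromosome 1 and 57780029 on chromosome 11 stood at 2.83 ± 0.446 and 2.62 ± 0.865 CPM (SD, n = 3), at least 14.18-fold and 10.81-fold higher than in fibroblasts. The largest falls were at 68959443 to 68960958 on chromosome 15, from 10.3 ± 2.11 to 0.500 ± 0.0508 CPM (log2 fold change -4.33, SE 0.41, adjusted p 1.70e-12 in edgeR), and at 45408145 to 45409956 on chromosome 1, from 13.6 ± 4.27 to 0.635 ± 0.284 CPM (-4.30, SE 0.38). The 33823 calls became 22143 without fibroblast replicate 1, 21337 under the stricter threshold and 16294 with no filter, and with library totals alone 88.8% rather than 56.8% were higher.

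**Figure D2:**
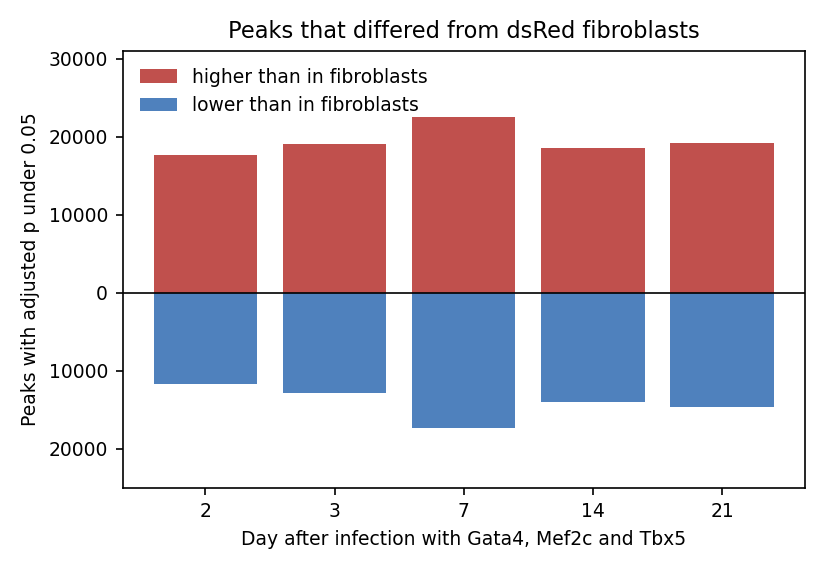
Number of peaks (y axis) with an adjusted p under 0.05 in edgeR's quasi-likelihood test against fibroblasts at each day (x axis), higher ones above and lower ones below the line at 0. Higher peaks outnumber lower ones at all 5 days, from 17683 against 11719 at day 2 to 19209 against 14614 at day 21.

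Peaks that differed from fibroblasts rarely had opposite directions at different times. Of all peaks tested, 30622 were higher than in fibroblasts at 1 or more of the 5 times and 24797 were lower at 1 or more, while 8 were higher at one time and lower at another. All 5 comparisons use the same fibroblast libraries, which by itself favours a shared direction, as in the simulated unchanged groups described below. The small number of opposite peaks is thus no measure of persistence. At all 5 times, 10317 were higher and 6596 lower, against 9944 and 7024 with RLE size factors and 17530 and 1731 with library totals alone. Of the peaks higher at day 2, 12413 (70.2%) were also higher at day 21, and of the lower ones 8419 (71.8%) were also lower. Independent lists of these sizes would share 2346 and 1183 peaks. Simulated unchanged groups set against the same fibroblast libraries had 0 calls at either time in edgeR in both of 2 runs (6826 and 6868 peaks at an unadjusted p under 0.05 for day 21), so they give no chance value for this overlap. Since 3 control libraries cannot be split with 2 in each part, part of the excess may come from the shared controls.

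Some of the persistent changes lay side by side, in windows chosen after their values were seen. Sums below are over all tested peaks of a window. In the 100000 bases of chromosome 14 from 35300001, 19 of 53 tested peaks were higher at all 5 times and 0 were lower at all 5, while 5 of the 53 fell from day 2 to day 21. The window sum went from 213 ± 4.16 CPM (SD, n = 3) in fibroblasts to 517 ± 182 at day 2 and 529 ± 110.1 at day 21. On chromosome 13 from 12000001, 18 of 53 peaks were higher throughout, with window sums of 63.6 ± 7.90, 180.4 ± 20.7 and 192 ± 28.1 CPM in these groups. On chromosome 1 from 71600001, 38 of 52 peaks were lower and 1 was higher at all 5 times, while 4 fell from day 2 to day 21. The window sum fell from 488 ± 38.3 to 169 ± 41.7 CPM at day 2 and 128 ± 13.1 at day 21. On chromosome 10 from 85800001, 18 of 27 peaks were lower throughout, with window sums of 253 ± 18.6, 65.3 ± 4.36 and 85.9 ± 8.69 CPM. In the neighbouring window of chromosome 10 from 85700001, 12 of 30 peaks were lower and 1 was higher at all 5 times. Its window sums were 215.7 ± 8.76, 120.3 ± 19.3 and 146 ± 26.75 CPM in these groups. With library totals alone it stood at a log2 ratio of -0.10 for day 21 over fibroblasts, where the median of all peaks was 0.66. Of 10648 windows with a tested peak, 422 held 5 or more peaks higher at all 5 times and 68 held 5 or more lower at all 5 times. These counts were 395 and 79 with RLE size factors and 1050 and 5 with library totals alone. No chance value was computed for them. Windows were ranked by the number of such peaks, which favours windows with many tested peaks.

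The size of the early change was compared with that of the late one. Over the 33823 peaks called at day 21 against fibroblasts, the median ratio of the day 2 to the day 21 log2 fold change was 0.846 (quartiles 0.614 and 1.065), and 98.15% had the same direction at both times. In simulated unchanged groups that share the fibroblast libraries, 93.7 and 93.4% of peaks with an unadjusted p under 0.05 at day 21 had the same direction, against 96.75% of the observed peaks chosen in that way. The median ratio over the simulated ones was 0.600 and 0.601. The observed ratio to day 21 was 0.876 at day 3, 0.993 at day 7 and 0.960 at day 14. By library of day 2, each taken alone, the share was 0.881, 0.850 and 0.835 for replicates 1, 2 and 3 (SD 0.0238). These 3 values were computed from log2 CPM with a prior count of 2 rather than from fitted fold changes. Simulated data in which day 2 equalled fibroblasts gave 0.0849 and 0.0846 over 46577 and 46923 peaks called at day 21. Data in which day 21 equalled day 2 gave 0.944 and 0.942 over 45857 and 45496 peaks. Both kinds thus had more calls than the 33823 observed. Across all peaks, which are not independent replicates, the correlation of both fold changes was 0.843 against 0.5675 and 0.572 for simulated unchanged groups, and the covariance was 1.05 against 0.153 and 0.155. With fibroblast replicate 3 as control for day 2 and replicates 1 and 2 for day 21 the share was 0.9185, and with these controls exchanged it was 0.777. The value to set beside these was 0.854, with all 3 fibroblast libraries as control for both days.

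**Figure D3:**
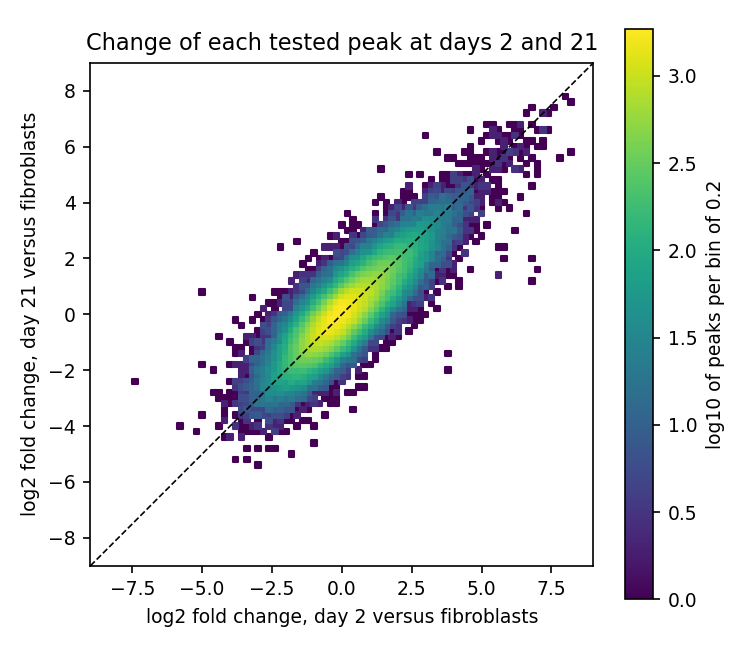
Log2 fold change of the 144810 tested peaks against fibroblasts at day 2 (x axis) and day 21 (y axis), with colour for the log10 number of peaks per bin and a dashed line where both are equal. The correlation across peaks was 0.843, and the same fibroblast libraries enter both axes.

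Comparisons between consecutive days, whose contrasts leave out the fibroblast groups, asked when accessibility moved among GMT cells. Between days 3 and 7, 12 peaks differed in edgeR, 2 of them higher and 10 lower at day 7, and 15 in DESeq2. Of the 10 that fell, 8 lay in a pair of short stretches, 6 between 83730819 and 83802523 on chromosome 13 and 2 between 63819108 and 63860065 on chromosome 14. Counts in these stretches do not tell reads of chromatin from reads of the delivered factor sequences. The falls are thus changes in read count. The largest falls were at 83764596 to 83765336, from 11.9 ± 5.99 to 1.28 ± 0.836 CPM (SD, n = 3; log2 fold change -3.03, SE 0.44, adjusted p 0.00228), and at 83772366 to 83773128, from 31.01 ± 18.95 to 3.70 ± 2.00 CPM (-3.02, SE 0.39, adjusted p 0.000106). The peak at 83602423 to 83604249 on chromosome 15 rose from 2.20 ± 1.49 to 7.44 ± 1.31 CPM (1.63, SE 0.32, adjusted p 0.0452), and its adjusted p ran from 0.0191 to 0.974 over the alternatives. The other peak that rose, at 126362477 to 126362879 on chromosome 10, went from 0.268 to 2.25 CPM and is below the level set for named peaks, so it was chosen after its values were seen. The 12 calls became 4 with no filter, with voom and without day 7 replicate 2, and 5 in a fit of both groups alone. Both named falls of chromosome 13 missed the threshold with voom (adjusted p 0.233 and 0.150) and without the libraries that stand apart (0.147 and 0.234), and the first also without day 7 replicate 2 (0.0552) or replicate 3 (0.0563), with adjusted p down to 4.07e-08 and 5.01e-08 under other alternatives.

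No peak passed the test between days 2 and 3, between days 7 and 14 or between days 14 and 21. edgeR and DESeq2 both called 0 peaks in each, and at an unadjusted p under 0.05 edgeR gave 5247, 10373 and 4757 of 144810 peaks. Simulated data in which day 21 equalled day 2 gave 6569 and 6647 such peaks between those days. Only the value for days 7 and 14 lay above these. For days 2 and 3, voom called 1 peak, as did the fit without the libraries that stand apart. For days 7 and 14, that fit called 22, and 9 were called without day 7 replicate 2 and 2 without day 14 replicate 2. At this depth changes of 2-fold or less between consecutive days were mostly not detectable. Larger ones could also be missed: the simulations recovered 52, 66 and 64% of 4-fold and 72, 78 and 74% of 8-fold changes in these comparisons.

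Over the longer interval from day 2 to day 21, 829 peaks rose and 1261 fell, 1.44% of those tested, with median log2 fold changes of 1.53 and -1.45. Of the 829, 614 (74.1%) were higher than in fibroblasts at day 21, and 494 of these were not called at day 2. Of the 1261, 783 (62.1%) were higher than in fibroblasts at day 2, and 558 of these were not called at day 21, while 342 (27.1%) were lower than in fibroblasts at day 21. The largest rises were on chromosome 14 at 55571939 to 55574039, from 0.810 ± 0.192 to 8.125 ± 1.91 CPM (SD, n = 3; log2 fold change 3.32, SE 0.40, adjusted p 1.14e-07 in edgeR), and at 55575169 to 55576060, from 0.367 ± 0.348 to 4.37 ± 0.955 CPM (3.12, SE 0.47). The largest falls were on chromosome 13 at 83772366 to 83773128, from 65.7 ± 37.3 to 1.33 ± 0.193 CPM (-5.61, SE 0.46), and at 83795713 to 83796137, from 43.5 ± 9.18 to 0.9395 ± 0.297 CPM (-5.42, SE 0.45). Both lie in the stretch where reads of delivered sequences were not told apart. DESeq2 called 1863 peaks in place of 2090, while library totals alone gave 503, the stricter threshold 652, no filter 53, and the fit without the libraries that stand apart 3209. The count was 1051 without day 2 replicate 2, 727 without day 2 replicate 3, 702 without day 21 replicate 1 and 723 without day 21 replicate 3.

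The 2 rising peaks lie in a stretch of chromosome 14 from 55555113 to 55580442, summed after their values were seen. Of its 14 tested peaks, 12 rose from day 2 to day 21, with a median log2 fold change of 2.89 over the 14. The summed accessibility of the 14 was 18.3 ± 1.21 CPM (SD, n = 3) in fibroblasts, 17.5 ± 5.63 at day 2, 19.7 ± 4.94 at day 3, 47.3 ± 4.08 at day 7, 62.0 ± 20.9 at day 14 and 104.5 ± 30.0 at day 21. On chromosome 13 from 12400001, 9 of 23 tested peaks rose after day 2, and 9 of the 23 were higher than in fibroblasts at all 5 times, with window sums of 88.6 ± 2.65 CPM in fibroblasts, 157 ± 21.15 at day 2 and 244 ± 53.2 at day 21. In the opposite direction, 9 of 20 peaks in the window of chromosome 13 from 22000001 fell after day 2, with window sums of 211 ± 12.5, 212 ± 1.74 and 128 ± 18.2 CPM in these groups, and 9 of 34 in that of chromosome 12 from 17000001, with 105 ± 1.86, 209.6 ± 42.99 and 139 ± 17.7 CPM.

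Among the 5 times together, 2785 peaks differed in edgeR's quasi-likelihood F test and 2464 in DESeq2's likelihood ratio test. The count was 134 with no filter, 1346 with library totals alone, 1083 under the stricter threshold and 4756 without the libraries that stand apart. It was 1695 without day 2 replicate 2, 1431 without day 2 replicate 3, 1784 without day 14 replicate 1, 1853 without day 21 replicate 1 and 1779 without day 21 replicate 3.

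**Figure D4:**
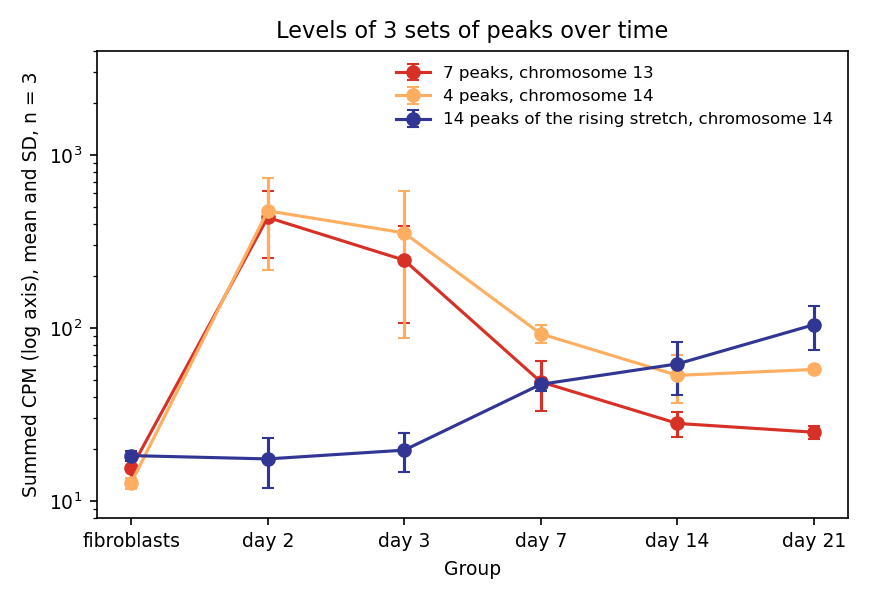
Summed CPM on a log axis (y axis; mean and SD of 3 libraries per group) by group (x axis) for 7 peaks of chromosome 13, 4 peaks of chromosome 14 and the 14 peaks of the rising stretch of chromosome 14. The first set went from 15.4 in fibroblasts to 435 at day 2 and 25.0 at day 21, while the rising stretch went from 17.5 at day 2 to 104.5 at day 21.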

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

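Of the tests below, the comparisons between times and the regroupings of libraries were planned, while those on the stretches of chromosomes 13 and 14, on the region of chromosome 1, and on how far thinning moves a library were chosen after the results were seen, apart from the correlation of both stretches, the level a thinned library reaches and the trended normalization, whose outcomes had not been seen. The change against fibroblasts differed between day 21 and day 2 at 2090 peaks, between day 7 and day 3 at 12 peaks, and among the 5 times at 2785 peaks, each by a test of the difference itself. For the 2785, 40 assignments of the 15 GMT libraries to times, the real one included, gave at most 607 peaks otherwise. As many peaks as the real one were thus found in 1 of 40 assignments, a share under 0.05. This argues against chance as the source of that count, but so few assignments cannot exclude it. For comparisons of 3 libraries with 3, the 10 possible splits are too few for a share under 0.05. The real and the highest other counts were 29402 and 0 at day 2 against fibroblasts, 31908 and 0 at day 3, 39820 and 0 at day 7, 32626 and 0 at day 14, and 33823 and 0 at day 21. They were 12 and 0 for day 7 against day 3, 2090 and 6 for day 21 against day 2, 0 and 2 for day 14 against day 7 and 0 and 1 for day 21 against day 14. For day 3 against day 2 they were 0 and 294, where the 4 splits that put the 2 libraries that stand apart together gave 0, 294, 0 and 29. The count of 294 points to a structure of the samples other than time, although placing those libraries together did not give such a count in each split. As many peaks as the real split were found in 1 of 10 splits in each of the comparisons with fibroblasts, day 7 against day 3 and day 21 against day 2, and in 10 of 10 where the real count was 0.

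The first pattern was a set of 11 peaks, 7 on chromosome 13 between 83730819 and 83802523 and 4 on chromosome 14 between 63819108 and 63860065, whose median log2 fold change was 5.67 at day 2 against fibroblasts and -3.805 from day 2 to day 21. Over all 40 tested peaks from the first to the last in each stretch, the median log2 change from day 2 to day 21 was -0.192 with quartiles of -2.15 and 0.20. Peaks that fell thus lie among others that did not. The 11 were chosen for their fall, and their number among the 40 by itself places the lower quartile among them. This test could therefore not exclude opening and closing of the chromatin there, which is neither shown nor excluded. The 29 others, which are set apart by the change itself, had a median log2 change of -0.061 from day 2 to day 21 (quartiles -0.259 and 0.371), with 0 called falls. Their median log2 fold change was 1.01 at day 2 against fibroblasts. The 18 of them on chromosome 14 summed to 43.2 ± 3.38 CPM (SD, n = 3) in fibroblasts, 88.9 ± 15.2 at day 2 and 104.9 ± 8.56 at day 21. The 11 on chromosome 13 summed to 32.9 ± 3.53, 36.97 ± 8.23 and 33.3 ± 3.675 CPM. Another candidate explanation is reads from the delivered factor sequences: levels of both stretches deviated together among the 9 libraries of days 2, 3 and 7 with Pearson's r of 0.487 and Spearman's rho of 0.433 (exact one-sided permutation within days, 216 arrangements, p = 0.176 and 0.218), and r was -0.13 without the 2 farthest libraries. These explanations cannot be told apart with 9 libraries and no annotation of mm9, which was not used here, to place the peaks on exons.

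The second pattern was the position of the day 2 and day 3 libraries with replicate number 1, with 2.29 and 2.95 M counts, on component 2. Low depth alone is argued against: the other libraries of these days, thinned to the same totals, covered at most 27.2% of the distance, of which thinning added at most 2.31 points, since the library in question already lay at 24.9% unthinned. The bound set beforehand for the first value was 25%, so it alone did not decide, and the second was examined afterwards. A trend with peak abundance is also argued against, since 91.0% of the distance was kept after trended normalization. Both libraries might share a preparation or a sequencing core, which the labels do not give, and no biological explanation was tested.

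The third pattern was 1 region of chromosome 1, at 24618407 to 24622986, that took 4.52 to 49.4% of a library's counts. The SD within groups was 1.36 times that of the group means, with 37.7 ± 20.1% (SD, n = 3) in fibroblasts and 10.8 ± 8.62% at day 21. Means of 3 libraries vary less than single libraries, so this ratio does not decide whether the groups differ. Mitochondrial reads placed on a nuclear copy are a candidate explanation: the share of the region at 98299295 to 98300094 on chromosome 12 followed it over the 18 libraries with Spearman's rho of 0.990 and Pearson's r of 0.944 (both permutation p = 1e-05, the smallest the shuffles can give), r of 0.982 without the 2 farthest and r of 0.968 for deviations within groups. Any other source of reads common to both regions would give the same relation.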

How the results depend on the processing

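Several alternatives were chosen after the data were seen: leaving out the libraries that stand apart, summing fibroblast replicates 1 and 2, leaving out the 5 regions with most counts, voom, splitting the controls, and all settings of the stretches and of the counts at all 5 times. Counts of peaks stayed within 1.5 times of those reported, and the share within its spread over day 2 libraries, in 12 of 12 results under RLE size factors, trended normalization, a filter at 1 CPM, the replicate block, without day 14 replicate 3, with fibroblast replicates 1 and 2 summed (24251, 26522, 33102, 27601 and 27973 calls against fibroblasts by day) and without the 5 highest regions, and in 11 of 11 with DESeq2. No named peak and no summed stretch reversed its direction under the alternatives applied to it. For the peaks behind the counts, reversal of single peaks was not tested.

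With no filter, which tests many more regions of low count, calls against fibroblasts were 11610, 15639, 21714, 13053 and 16294 at days 2, 3, 7, 14 and 21, with 4 for day 7 against day 3, 53 for day 21 against day 2 and 134 among the 5 times. The stricter threshold gave 17575, 20012, 24876, 20775 and 21337, then 652 for day 21 against day 2 and 1083 among the 5 times, fewer by construction. Library totals alone gave 503 for day 21 against day 2, 1346 among the 5 times and a share of 0.892, moved peaks higher and lower at all 5 times to 17530 and 1731 and windows with 5 or more of them to 1050 and 5 (9944, 7024, 395 and 79 with RLE size factors), and raised the median log2 change of all peaks against fibroblasts to 0.63, 0.51, 0.30, 0.58 and 0.66. Without the libraries that stand apart there were 1 call for day 3 against day 2, 22 for day 14 against day 7, 3209 for day 21 against day 2 and 4756 among the 5 times. Voom gave 1 for day 3 against day 2 and 4 for day 7 against day 3, and the fit of both groups alone 5 for the latter. Split controls gave shares of 0.9185 and 0.777, against 0.854 with all 3 controls for both days. Library totals include the chromosome 1 region, which held a mean of 37.7% of counts in fibroblasts and 10.8 to 27.2% at the GMT times. A larger share there lowers all other peaks of a library under that scaling. Except where the construction shows it, the cause was not tested.

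Leaving out each library gave 18750 to 26536 calls at day 2, 20578 to 31002 at day 3, 25718 to 34638 at day 7, 21876 to 31630 at day 14 and 22143 to 30198 at day 21 against fibroblasts. It gave 0 to 0 for day 3 against day 2 and for day 21 against day 14, 4 to 13 for day 7 against day 3, 0 to 9 for day 14 against day 7, 702 to 1989 for day 21 against day 2, and 1431 to 3667 among the 5 times. The share was 0.838 to 0.858 when 1 replicate number was left out of all groups at once. It was not computed without single libraries. Lowest values against fibroblasts came without fibroblast replicate 1 at days 2, 3, 7 and 21.

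With the replicate block, calls against fibroblasts were 28526, 30720, 38745, 31968 and 32674, consecutive ones 0, 11, 0 and 0, those of day 21 against day 2 2149, those among the 5 times 2573, and the share 0.845, so no call changed by over 1.5 times. In no comparison were all 3 correlations of same-numbered libraries over 0.1, the bound for pairing, so the numbers were not taken to pair the samples. For days 2 and 3 they were 0.321, 0.214 and 0.0985, and 3 of 6 libraries correlated best with their own number.

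Of 540 values for 27 pairs of a named peak and a comparison, which cover 18 peaks, 521 kept their side of the threshold and 19, for 3 peaks of day 7 against day 3, lost it. Of 75 values for 15 summed stretches, 70 moved by less than the spread and 5, all with library totals alone, by more. Depth limits single peaks: the median count per tested peak was 4 in fibroblast replicate 3 and 34 in day 3 replicate 3.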

Other observations

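The hypothesis below and its test were chosen after the results were seen, as were the windows. Of 10648 windows of 100000 bases, 337 held 2 or more peaks higher and 2 or more lower at all 5 times, with no chance value computed. On chromosome 13 from 21300001, 6 of 19 tested peaks fell after day 2 and 3 of the 19 were higher than in fibroblasts at all 5 times, and the window sum went from 159.5 ± 3.98 CPM (SD, n = 3) in fibroblasts and 145 ± 12.5 at day 2 to 81.8 ± 10.9 at day 21. On chromosome 1 from 72900001, 7 of 25 peaks rose after day 2 and 7 of the 25 were higher than in fibroblasts at all 5 times, with window sums of 61.95 ± 2.67, 91.7 ± 8.37 and 191 ± 20.8 CPM in these groups.

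A hypothesis from these windows is that peaks change in domains wider than 1 peak. Of 33814 pairs of consecutive called peaks on a chromosome at day 21 against fibroblasts, 67.15% had the same direction, against a mean of 51.4% and a maximum of 52.2% in 1000 shuffles of the directions within chromosomes (permutation p = 0.001, the smallest they can give). At day 2 it was 68.6% against a mean of 52.5%, and for day 21 against day 2 64.7% against 52.0%. Shared direction in neighbours may also arise where 1 broad accessible region was divided into several peaks, which was not tested.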
